A study of Mus musculus with 6 samples.

How the data were processed

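Bulk RNA sequencing was done on day 7 wound skin from C57BL/6 male mice, 3 samples treated with CMC and 3 with CMC + COL17-5. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads, stranded libraries were made by random priming and sequenced as paired ends on a NovaSeq X Plus. Poly(A) selection leaves transcripts without a poly(A) tail under-counted, and counts from fragmented RNA rise with transcript length. The submitters' processing notes name fastp, HISAT2, StringTie and RSEM and the genome build GRCm39, with no versions, order or settings.

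The authors deposited a table of estimated counts per gene (expected counts, 78317 genes) and a table of FPKM for the same genes. The expected counts were not scaled for depth, as judged from their totals, which differ between libraries. Of the values above 0, 75.0 to 77.2% per library were whole within 1e-09 (91.4 to 92.5% with zeros included), and fractional values come from reads divided between genes or transcripts, so genes with near-identical copies have uncertain levels. The deposited FPKM values are scaled by the authors for gene length and depth. They were used here as an alternative unit. Both tables also hold the authors' group means, which were not used here. Gene symbols, biotypes and annotation terms are those in the tables: 56408 rows had a symbol, and 21909 kept the Ensembl identifier. The genome given here was an older build than the authors', so no coordinates are printed.

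Samples were grouped by the labels, which give the group and a replicate number. Expected counts were rounded to whole numbers. Total counts were 19126347, 18067856 and 17962372 for CMC replicates 1 to 3 and 18990730, 19259578 and 19471003 for CMC + COL17-5 replicates 1 to 3. Counts of library pairs within a group differed far beyond sampling noise, so no library was counted as a copy of another. edgeR 4.0.16 in R 4.3.3 was run with TMM factors, filterByExpr defaults and a quasi-likelihood F test of group, two-sided, on all 6 samples. Of the genes, 17199 passed the filter, 14737 of them protein-coding. P-values were adjusted by Benjamini-Hochberg and a gene was called at an adjusted p under 0.05. The standard error is the size of the log2 fold change divided by the square root of F, and its median over genes was 0.16. CPM values use the TMM-scaled library sizes, and errors are SD over 3 samples. The common dispersion was 0.038 and the prior degrees of freedom 3.31.

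A total of 41 gene lists for epidermis, dermis, immune and vascular cells, other tissues, signalling and RNA handling was fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01, Benjamini-Hochberg over lists, and again with the correlation estimated from the data. Members were also counted after adjustment over the list alone. fry was run for both directional and mixed change. Some genes belong to several lists. Markers describe transcripts of the tissue, not counted cells. Principal components used log2 CPM with a prior count of 2.

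Named genes followed a rule fixed before the data were examined: Col17a1, then, since no gene was called, the 5 genes with the smallest p in each direction among genes with a mean count of at least 50 and groups that do not overlap, and of each described list the 2 members with the highest mean CPM. The rule did not say whether a gene without a symbol counts when no gene is called, so the 1 such gene with a p-value among the smallest is named as well. For space, the 2 highest members are not given for most lists that were not called, which departs from the rule. Other genes named were chosen after their values were seen.

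The gene test and the list test were tested on simulated data for this comparison, with 200 genes changed. Counts of genes that passed the filter were drawn from the real means, dispersions and library sizes. Low-count genes, which entered the unfiltered run, were drawn around their mean count with sampling noise alone and no scaling to library size. With edgeR on 17193 genes, 7.46% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, and 9 of 116 calls were of unchanged genes. DESeq2 gave 51 unchanged genes among 190 calls, and edgeR without the low-count filter, on 33818 genes, 56 among 182. The simulated genes were independent, so the effect of correlated genes on the list test was not covered.

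Alternatives fixed before the data were examined were other scaling factors, DESeq2 1.42.0, limma-voom with and without quality weights, robust shrinkage, no filter on low counts, a filter of CPM at least 1 in 3 samples, the replicate number as a block, leaving out each sample, a size threshold of 1 on the log2 scale, an adjusted p under 0.1, protein-coding genes only, limma on log2 FPKM with pseudocounts of 0.1 and 1 and with or without a minimum mean FPKM of 0.5, removal of the muscle, fat and hair lists, and list tests without genes shared between lists. Fold changes on the log2(FPKM + pseudocount) scale understate the change of low genes. Annotation terms were tested by Fisher's exact test, one-sided, for terms of 10 to 500 genes, where a setting called genes. Figures were drawn with matplotlib 3.10.9.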

Results

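Wound skin was profiled by RNA sequencing in 6 male C57BL/6 mouse samples taken on day 7 after a full-thickness wound of 10 mm diameter was made on the back at 7 weeks of age. Wounds received a daily topical application of either CMC (3 samples) or CMC + COL17-5 (3 samples). The labels spell out neither name, and the series title speaks of type XVII collagen, a transmembrane collagen of the hemidesmosomes that anchor basal keratinocytes to the dermis. Total estimated counts per library lay between 17962372 and 19471003. The labels do not say that the 3 samples of a group came from separate mice, so p-values measure the spread between these samples, which may be partly technical.

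The first 3 principal components of log2 CPM held 28.1%, 26.7% and 18.7% of the variance. On the first, CMC replicates 1 to 3 lay at -39.9, -0.75 and -20.5 and CMC + COL17-5 replicates 1 to 3 at 32.4, 3.76 and 24.9, so the groups did not overlap, which chance gives in 10% of cases for 1 axis. Replicate 2 of each group lay close to 0. The groups overlapped on the other 2. Pearson correlations across genes ranged from 0.972 to 0.980 for the 6 pairs of libraries within a group, and from 0.968 to 0.979 for the 9 pairs between groups.

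The design compares wounds given CMC + COL17-5 with wounds given CMC alone. The animal's own Col17a1 (ENSMUSG00000025064) stood at 120 ± 22.0 CPM in CMC and 131 ± 36.7 CPM in CMC + COL17-5 (SD, n = 3), a log2 fold change of 0.13 (SE 0.23, edgeR adjusted p = 0.991) that lay within the spread between replicates. That log2 fold change was -0.02 without CMC + COL17-5 replicate 2, 0.34 without CMC + COL17-5 replicate 3, 0.28 and 0.01 without CMC replicates 1 and 2, and 0.04 without CMC + COL17-5 replicate 1. Among genes with a mean count of at least 50 whose groups did not overlap, the 5 with the smallest p-values on the higher side were the chaperone genes Hsph1, Hspa1b and Hspa1a, the clock gene Per1 and the long noncoding RNA gene Lincmd1. On the lower side the genes with the smallest p-values included Srgn, which encodes the granule proteoglycan serglycin, and Slc2a3, which encodes a glucose transporter. None of these passed edgeR's adjustment over all genes, while DESeq2 called them all and edgeR without the low-count filter all but Lincmd1. Counts of members over all genes given for lists below are edgeR's with the filter unless another tool is named. Transcripts of inflammatory mediators and neutrophils were lower in CMC + COL17-5 as lists with a preset correlation between genes (adjusted p = 4.55e-23 and 4.99e-23), but adjusted p = 0.313 with an estimated correlation for both. Of their members 13 and 10 passed adjusted over the list alone and 0 over all genes with edgeR, against 8 and 6 over all genes with DESeq2.

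edgeR's quasi-likelihood test called 0 of 17199 genes between the treatments, with a smallest adjusted p of 0.220. At an unadjusted p under 0.05 there were 876 genes, 427 higher and 449 lower in CMC + COL17-5, where chance gives 860. The groups did not overlap in 1851 genes, or 10.8%, where chance gives 10%. limma-voom called 0 genes with and without sample quality weights, and limma on log2(FPKM + 0.1) called 1. DESeq2 called 69 genes, 15 higher and 54 lower, and edgeR without the low-count filter called 50, 7 higher and 43 lower. In data simulated from these libraries, 26.8% of DESeq2's calls and 30.8% of those without the filter were of unchanged genes, against 7.76% for edgeR with the filter. The low-count genes of the unfiltered run were simulated with sampling noise alone, so its share may differ in the real data. No gene was called by edgeR, so enrichment of annotation terms among called genes could not be tested with it.

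Hsph1 (ENSMUSG00000029657), a cytosolic chaperone of the HSP110 family, had 56.2 ± 6.31 CPM in CMC and 112 ± 7.45 CPM in CMC + COL17-5, a log2 fold change of 0.99 (SE 0.11, adjusted p = 0.220). Per1 (ENSMUSG00000020893), a repressor in the circadian clock, went from 34.7 ± 4.65 to 71.5 ± 5.87 CPM, a log2 fold change of 1.04 (SE 0.12, adjusted p = 0.220). The heat shock genes Hspa1b (ENSMUSG00000090877) and Hspa1a (ENSMUSG00000091971) had log2 fold changes of 0.80 and 0.83, and their levels are uncertain one by one because they are near-identical copies. The long noncoding RNA Lincmd1 (ENSMUSG00000099906) had a log2 fold change of 1.14 at 2.73 and 6.04 CPM. On the lower side, Ankrd33b (ENSMUSG00000022237) had a log2 fold change of -1.37 (SE 0.16, adjusted p = 0.220) and Tiparp (ENSMUSG00000034640), a target of the aryl hydrocarbon receptor, one of -0.66 (SE 0.08, adjusted p = 0.259). The long noncoding RNA ENSMUSG00000141229, which has no symbol, had a log2 fold change of -2.50 (SE 0.30, adjusted p = 0.220) at 7.51 ± 2.16 CPM in CMC and 1.33 ± 0.334 CPM in CMC + COL17-5. Srgn (ENSMUSG00000020077) had 230 ± 51.8 CPM in CMC and 90.8 ± 8.92 CPM in CMC + COL17-5, Slc2a3 (ENSMUSG00000003153) 50.1 ± 15.4 and 13.5 ± 3.51 CPM, and Hcar2 (ENSMUSG00000045502), a receptor for hydroxy-carboxylic acids, 116 ± 50.0 and 26.4 ± 6.66 CPM. Their log2 fold changes were -1.34, -1.89 and -2.14, with adjusted p of 0.323, 0.378 and 0.378. DESeq2 called these 11 genes (adjusted p = 3.44e-09 for Hsph1, 3.03e-08 for Per1 and 0.00355 for Lincmd1), and edgeR without the filter called 10 of them, all but Lincmd1. In each of the 11 all 3 libraries of one group lay above all 3 of the other, which is also how they were selected.

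**Figure D1:**
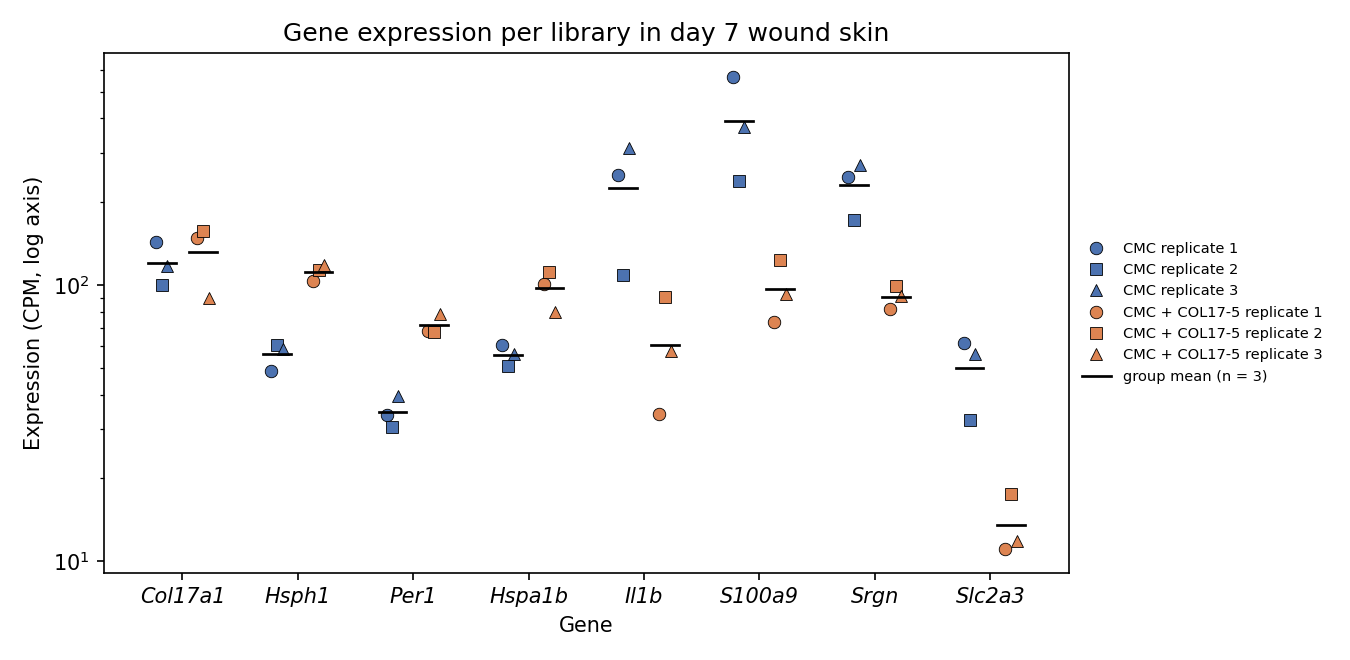
Expression in CPM (log axis) of 8 genes in each of the 6 libraries, with circles, squares and triangles for replicates 1, 2 and 3 and black lines for group means (n = 3). Libraries of the groups overlap for Col17a1 and do not overlap for the other 7 genes, none of which passed edgeR's adjustment over all genes and all of which DESeq2 called.

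Inflammatory cytokine and chemokine genes were lower in CMC + COL17-5, with 22 of 24 tested members below 0 and a median log2 fold change of -1.14. The list was called by camera (adjusted p = 4.55e-23), but adjusted p = 0.313 with an estimated correlation. 13 members, all lower, passed adjusted over the list alone and 0 passed over all genes with edgeR. DESeq2 and edgeR without the filter each called 8 members over all genes, Cxcl2, Il1b and Ptgs2 among them. The neutrophil attractant Cxcl2 had 205 ± 85.3 CPM in CMC and 35.2 ± 14.9 CPM in CMC + COL17-5, Il1b, which encodes interleukin-1 beta, 224 ± 105 and 60.7 ± 28.2 CPM, and Ptgs2, the inducible cyclooxygenase, 50.2 ± 22.2 and 14.4 ± 6.64 CPM. Spp1, the most abundant member, stood at 594 ± 117 and 521 ± 220 CPM. The monocyte attractants Ccl2 and Ccl7 had log2 fold changes of -0.30 and -0.26 and did not pass. The count of 13 was 7 without CMC + COL17-5 replicate 1 and 8 without CMC + COL17-5 replicate 3.

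Neutrophil transcripts were also lower as a list, with 21 of 23 tested members below 0 and a median log2 fold change of -0.98. camera called the list (adjusted p = 4.99e-23), with adjusted p = 0.313 with an estimated correlation. 10 members, all lower, passed adjusted over the list alone and 0 over all genes with edgeR. DESeq2 called 6 over all genes and edgeR without the filter 5, both with S100a9, S100a8, Clec4e and Clec4d. S100a9 and S100a8, which encode the subunits of calprotectin, had 392 ± 165 and 213 ± 84.9 CPM in CMC and 96.7 ± 25.1 and 58.5 ± 17.6 CPM in CMC + COL17-5. The lectin receptor genes Clec4e and Clec4d had log2 fold changes of -2.20 and -1.59. Granule protein genes of immature neutrophils did not pass, with Ngp, Ltf and Camp at log2 fold changes of -0.90, -0.63 and -0.59 and under 6 CPM. The count of 10 depended on single libraries, at 4 and 5 without CMC replicates 1 and 3, and 6, 5 and 5 without CMC + COL17-5 replicates 1, 2 and 3. On all 6 samples it was 6 with limma-voom and 15 without the low-count filter. With the replicate block 11 lower members and 1 higher member passed.

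Other leukocyte lists moved less. Of 25 monocyte and macrophage genes, with a median log2 fold change of -0.08, 1 passed adjusted over the list alone and 0 over all genes with edgeR. That gene, which DESeq2 and edgeR without the filter called, was Cd14, the co-receptor for lipopolysaccharide, with 210 ± 78.8 CPM in CMC and 63.0 ± 8.66 CPM in CMC + COL17-5. It was not among those passing without CMC replicate 1, CMC + COL17-5 replicate 1 or CMC + COL17-5 replicate 2 (0 genes each). The macrophage genes Lyz2 and Ctss stood at 2656 ± 344 and 474 ± 74.6 CPM in CMC and at 2503 ± 454 and 511 ± 123 CPM in CMC + COL17-5. The macrophage median was -0.21 without CMC + COL17-5 replicate 3, -0.17 and 0.02 without CMC replicates 2 and 3, and -0.01 without CMC + COL17-5 replicate 2. Repair-associated macrophage genes had a median of -0.17, T and NK lymphocyte genes 0.11, Langerhans and dendritic cell genes 0.11, and B and plasma cell genes -0.37 over 8 members. camera called none of these 5 lists (adjusted p from 0.0586 to 0.626, and from 0.877 to 0.938 with an estimated correlation). Leaving out 1 library gave a call to each: macrophage without CMC replicate 2 (adjusted p = 6.13e-07) or CMC + COL17-5 replicate 3 (3.52e-06), and repair-associated without CMC replicates 1 or 2 (0.0323 and 0.0236) or CMC + COL17-5 replicate 1 (1.48e-05). The others were T and NK without CMC replicate 1 (0.0224), B and plasma without CMC replicate 1 or CMC + COL17-5 replicate 1 (0.0149 and 0.0368), and dendritic without CMC + COL17-5 replicates 2 or 3 (0.0068 and 0.0499). On all 6 samples camera called the macrophage list lower with DESeq2 (0.0341), quality weights (0.00465), no low-count filter (0.0156), total counts only (0.0475) and the replicate block (0.0286), all with the preset correlation, but adjusted p = 0.938 with an estimated correlation. It called the repair-associated list with quality weights and no filter (0.0245 and 0.0183) and with genes of 1 list only (0.0496), but adjusted p = 0.877 with an estimated correlation. It also called the B and plasma list without the filter (0.00695, and 0.0117 on log2 FPKM), and the dendritic list with DESeq2 (0.0237) and genes of 1 list only (0.0496). The mast cell and basophil list was called lower (median -0.20, 7 of 12 tested members below 0, adjusted p = 0.0141, but adjusted p = 0.877 with an estimated correlation). Its 1 member passing adjusted over the list alone, called over all genes by DESeq2 and by edgeR without the filter, was Hdc, the histamine-forming decarboxylase, at 74.0 ± 37.9 and 18.1 ± 5.99 CPM, while the mast cell protease gene Mcpt4 stood at 60.1 ± 2.14 and 48.7 ± 14.9 CPM. The mast cell call ended without CMC replicate 3 and without CMC + COL17-5 replicates 2 and 3 (adjusted p = 0.0748, 0.0766 and 0.0817), and on all 6 samples with limma-voom (0.0505) and unfiltered log2 FPKM (0.145). Its median was -0.10 without CMC + COL17-5 replicate 3 and -0.13 without CMC replicate 2. The 1 passing member became 0 without CMC replicates 1 and 3 and CMC + COL17-5 replicate 3, and 3 without CMC + COL17-5 replicate 1. With the replicate block on all 6 samples the count was also 0.

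Heat shock and immediate early genes, grouped in 1 list of 24, went in opposite directions. 9 members passed adjusted over the list alone and 0 over all genes with edgeR, while DESeq2 called 3 higher and 4 lower over all genes and edgeR without the filter 3 and 3. Higher in CMC + COL17-5 were Hsph1, Hspa1b and Hspa1a. Lower were the immediate early genes Junb, Fosl1, Ier2, Ier3 and Nr4a1 and the phosphatase gene Dusp1, with log2 fold changes of -0.76, -1.47, -0.34, -1.10, -1.08 and -0.89. Fos, Jun and Egr1 did not pass and had log2 fold changes of -0.63, -0.09 and -0.08. The most abundant members, the chaperone genes Hspa8 and Hsp90aa1, had 1419 ± 121 and 208 ± 57.9 CPM in CMC and 1818 ± 178 and 280 ± 24.3 CPM in CMC + COL17-5 and did not pass. camera did not call the list (adjusted p = 0.529), whereas fry's test for change in either direction did (adjusted p = 0.00763, directional adjusted p = 0.991). Without CMC replicate 2 camera called it (adjusted p = 0.0447), but adjusted p = 0.938 with an estimated correlation on all 6 samples. Its median of -0.11 was -0.07 without CMC replicate 1 or 3, and -0.06 and -0.19 without CMC + COL17-5 replicates 2 and 3.

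Transcripts of tissues that can be taken along with wound skin differed between libraries. Skeletal muscle genes were below 0 in 30 of 30 tested members, with a median log2 fold change of -1.07. The list was called by camera (adjusted p = 9.52e-20), but adjusted p = 0.760 with an estimated correlation, and 0 members passed adjusted over the list alone or over all genes. The list took 1.36 ± 0.559% of counts in CMC and 0.676 ± 0.426% in CMC + COL17-5, led by Acta1 with 2558 ± 797 and 1281 ± 964 CPM and Atp2a1 with 1494 ± 571 and 692 ± 482 CPM. Its median was -0.68 without CMC replicate 2, which had the highest share (2.01%), and -1.61 without CMC + COL17-5 replicate 2, where 19 members passed adjusted over the list alone. That count was also 19 with the replicate number as a block and 21 without the low-count filter, and 0 in the other settings. Erythrocyte and platelet genes had a median of -0.99 over 10 members (camera adjusted p = 5.15e-11, but adjusted p = 0.313 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes, against 6 over the list alone without CMC + COL17-5 replicate 1 and 2 without CMC replicate 2. That count was 8 without the low-count filter, 7 with the block, 5 with DESeq2, 6 with limma-voom, 7 with its quality weights and 6 on log2 FPKM with the low-value filter. The 4 adult haemoglobin genes took 0.155 ± 0.0316% of counts in CMC and 0.0782 ± 0.0492% in CMC + COL17-5, with Hbb-bs at 707 ± 107 and 342 ± 218 CPM and Hba-a2 at 457 ± 89.8 and 236 ± 138 CPM. Haemoglobin genes share reads with near-identical copies. Hair follicle keratin and keratin-associated protein genes were above 0 in 28 of 28 members, with a median of 1.38 (camera adjusted p = 4.83e-14, but adjusted p = 0.877 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. Krt71 stood at 290 ± 157 and 474 ± 182 CPM and Tchh at 174 ± 115 and 375 ± 182 CPM. Without the low-count filter 16 hair genes passed over the list alone, and 0 in the other settings. The hair median was 0.35 without CMC + COL17-5 replicate 1, 0.90 without CMC replicate 1 and 2.19 without CMC replicate 3.

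**Figure D2:**
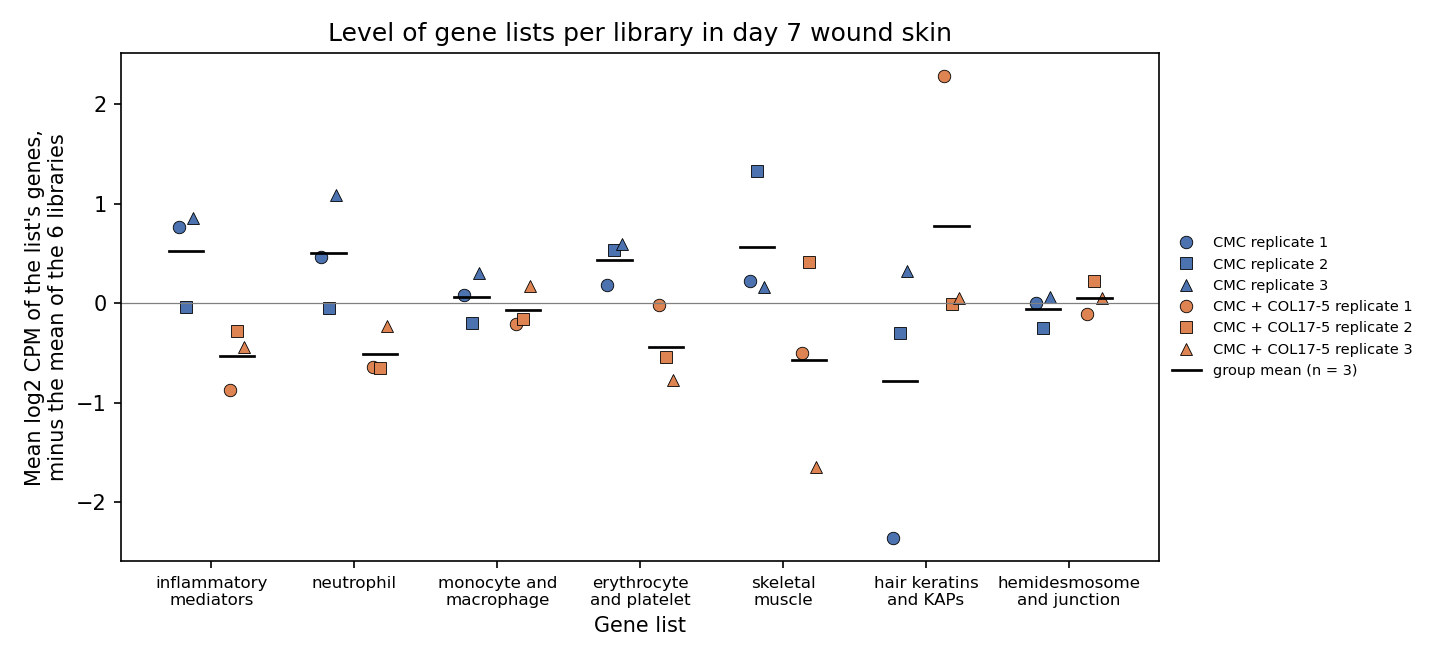
Mean log2 CPM of the genes of 7 lists in each of the 6 libraries, as the difference from the mean of all 6, with symbols for replicates as labelled and black lines for group means (n = 3). The groups do not overlap for the inflammatory, neutrophil and erythrocyte lists and overlap for the other 4, and the hair list is spread by CMC replicate 1 at -2.36 and CMC + COL17-5 replicate 1 at 2.28. Of all 41 lists, the groups do not overlap in 5, where chance gives 10%.

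Epidermal genes showed no called list among those of the basal layer and its anchorage. The median log2 fold change was 0.09 for basal keratinocyte genes, 0.13 for hemidesmosome and dermal-epidermal junction genes, 0.09 for epidermal differentiation, 0.11 for desmosome and tight junction, 0.01 for the skin lipid barrier and 0.14 for hair follicle stem cell genes, and camera's adjusted p ranged from 0.0792 to 0.923. In these 6 lists 0 members passed adjusted over the list alone or over all genes. Krt14 and Krt5, the keratins of the basal layer, stood at 1445 ± 656 and 944 ± 193 CPM in CMC and at 1594 ± 634 and 1138 ± 346 CPM in CMC + COL17-5. The basement membrane genes Col4a1 and Nid1 had 996 ± 134 and 741 ± 86.1 CPM in CMC and 1039 ± 189 and 773 ± 96.6 CPM in CMC + COL17-5, and the suprabasal keratins Krt10 and Krt1 1200 ± 345 and 868 ± 412 against 1365 ± 442 and 1048 ± 455 CPM. Without CMC + COL17-5 replicate 3 camera called the basal, desmosome, differentiation, lipid barrier and stem cell lists (adjusted p = 0.000593, 8.39e-08, 1.43e-07, 0.000758 and 0.00533). It also called differentiation without CMC replicates 1 or 3 (0.00249 and 0.0159), and the hemidesmosome list without CMC replicates 1 or 3 (0.0313 and 0.0132) or CMC + COL17-5 replicate 1 (0.00526). With an estimated correlation the adjusted p of these 6 lists was 0.877 or more. The basal median was 0.14 without CMC replicate 1 and 0.01, 0.00 and 0.26 without CMC + COL17-5 replicates 1, 2 and 3. The hemidesmosome median was 0.02 without CMC replicate 2 and 0.21 and 0.07 without CMC + COL17-5 replicates 1 and 2. Wound-activated keratinocyte genes were called lower by camera (median -0.23, 20 of 22 members below 0, adjusted p = 5.32e-06, but adjusted p = 0.877 with an estimated correlation). The 4 members passing adjusted over the list alone were S100a8, S100a9, Slpi and Il1rn, genes that neutrophils and macrophages are also known to express, and 0 passed over all genes with edgeR, while DESeq2 and edgeR without the filter called all 4. The keratins of the activated epidermis Krt6a, Krt6b and Krt16 had log2 fold changes of -0.05, -0.17 and -0.11, Lgals7 one of -0.10, and without CMC replicate 3 the list's median was 0.34 and the call ended. The median was -0.60 without CMC replicate 2, where 7 members passed over the list alone, and -0.38 without CMC + COL17-5 replicate 2. It was -0.09 with limma-voom, -0.14 with its quality weights, -0.10 with the block and -0.06 on log2 FPKM with the low-value filter. The call also ended with genes of 1 list only (0.0974). Antimicrobial genes had a median of -0.15 (camera adjusted p = 0.0117, but adjusted p = 0.877 with an estimated correlation), and the 3 members passing adjusted over the list alone were again S100a8, S100a9 and Slpi, with 0 over all genes with edgeR and 3 with DESeq2. Its highest members, Lyz2 and Hp, did not pass, and the camera call ended without CMC replicate 3 (median 0.11) and without CMC + COL17-5 replicate 2 (median -0.14). The median was -0.05 without CMC replicate 1 and -0.27 without CMC + COL17-5 replicate 1. On all 6 samples it ended with limma-voom (0.157), the replicate block (0.0888) and log2 FPKM (0.195 to 0.415, with a median of 0.07 with the small pseudocount). The list turned higher with genes of 1 list only (0.672).

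Genes of the dermal matrix were led by collagens. Col3a1 and Col1a1, the main fibrillar collagens, stood at 29571 ± 5539 and 22236 ± 4950 CPM in CMC and at 29445 ± 5221 and 25380 ± 6431 CPM in CMC + COL17-5. Median log2 fold changes were 0.03 for fibrillar collagens and their modifying enzymes, 0.03 for elastic fibre and matrix glycoprotein genes, 0.03 for myofibroblast and contraction genes and -0.13 for fibroblast markers (16 of 18 below 0, groups not overlapping in the list's mean, where chance gives 10%), with camera adjusted p from 0.0633 to 0.987. Matrix-degrading protease genes were called lower (median -0.12, adjusted p = 0.0336, but adjusted p = 0.938 with an estimated correlation), with Mmp2 at 1332 ± 338 and 1235 ± 138 CPM and its inhibitor Timp2 at 1296 ± 78.8 and 1229 ± 45.7 CPM, and that call ended without CMC replicate 3 (median -0.05) and without CMC + COL17-5 replicates 1 and 2 (medians -0.08 and -0.14). The protease median was -0.23 without CMC replicate 2 (3.68e-06) and -0.08 without CMC replicate 1. In these 5 lists 0 members passed adjusted over the list alone or over all genes, and 2 protease genes passed over the list alone without CMC replicate 2, with DESeq2 and without the low-count filter. The protease call also ended with limma-voom (0.0704), log2 FPKM (0.0761 to 0.145) and genes of 1 list only (0.0741). camera called the collagen list higher without CMC replicates 1 or 3 or CMC + COL17-5 replicate 1 (medians 0.12, 0.13 and 0.20, adjusted p = 0.0357, 0.0197 and 0.00013), but adjusted p = 0.996 with an estimated correlation on all 6 samples. The collagen median was -0.12 without CMC replicate 2 and -0.07 and -0.03 without CMC + COL17-5 replicates 2 and 3. camera called the fibroblast list lower without CMC replicates 1 or 2 or CMC + COL17-5 replicates 1 or 3 (0.0224, 0.0236, 0.0195 and 0.0194), with quality weights (0.0245) and without the filter (0.0185). With an estimated correlation on all 6 samples its adjusted p was 0.877. The elastic fibre and myofibroblast lists were called lower without CMC replicate 2 (0.0236 and 0.0249) and higher without CMC + COL17-5 replicate 1 (0.0368 and 0.0184). Both had adjusted p = 0.996 with an estimated correlation on all 6 samples.

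Glycolysis and hypoxia genes were lower in 20 of 23 members, with a median log2 fold change of -0.18. The list was called by camera (adjusted p = 8.38e-06), but adjusted p = 0.691 with an estimated correlation, and 0 members passed adjusted over the list alone or over all genes, against 5 over the list alone without CMC + COL17-5 replicate 2 and 1 without CMC replicate 2. DESeq2 and edgeR without the filter each gave 5 over the list alone and 1 over all genes, the lactate transporter gene Slc16a3. The glycolytic enzyme genes Gapdh and Aldoa stood at 1205 ± 64.1 and 1152 ± 137 CPM in CMC and at 810.0 ± 159 and 753 ± 243 CPM in CMC + COL17-5. Skeletal muscle, which is rich in these enzymes, took the smaller share of counts in the same group. Ribosomal protein genes had a median of -0.09 (camera adjusted p = 0.0406, but adjusted p = 0.938 with an estimated correlation), with Rplp0 at 1740 ± 140 and 1597 ± 161 CPM and Rps2 at 1504 ± 176 and 1364 ± 125 CPM. That call ended without CMC replicate 1 or 3 (medians -0.04 and -0.08) and without CMC + COL17-5 replicate 2 or 3 (median -0.05 each). It also ended on all 6 samples with total counts only (0.0592), the CPM filter (0.0513), protein-coding genes only (0.0527), the block (0.0882) and unfiltered log2 FPKM (0.086). The ribosomal median went the other way, to -0.16 without CMC replicate 2 (adjusted p = 0.000708) and -0.17 without CMC + COL17-5 replicate 1 (0.000342). 0 members passed adjusted over the list alone or over all genes.

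The other lists were not called by camera, with adjusted p from 0.0822 to 0.987. Cell division genes had a median log2 fold change of 0.00, with Pcna at 117 ± 3.55 and 117 ± 4.48 CPM and Top2a at 119 ± 10.5 and 114 ± 5.94 CPM. Medians were -0.02 for blood endothelium, -0.02 for lymphatic endothelium, 0.01 for pericytes and vascular smooth muscle, 0.04 for adipocytes, -0.07 for sebocytes, 0.13 for melanocytes and 0.12 for Schwann cells and nerve. They were 0.01 for the EGF, FGF and HGF families, 0.01 for TGF-beta and BMP signalling, 0.02 for Wnt signalling, 0.04 for Notch signalling, 0.02 for the interferon response and -0.18 for mitochondrially encoded genes. Among these 14 lists the 1 member that passed adjusted over the list alone was Cd274, which encodes the immune checkpoint ligand PD-L1, in the interferon list (log2 fold change -0.83), and 0 passed over all genes with edgeR, while DESeq2 and edgeR without the filter called Cd274. Leaving out 1 library gave a call to 8 of the 14: mitochondrial without CMC replicates 1 or 3 or CMC + COL17-5 replicate 1 (adjusted p = 0.00041, 0.00262 and 0.0368), interferon without CMC replicates 2 or 3 or CMC + COL17-5 replicate 1 (0.0156, 0.0159 and 0.0195), adipocyte without CMC replicate 3 or CMC + COL17-5 replicate 2 (0.000267 and 0.0068), and Schwann without CMC replicate 2 or CMC + COL17-5 replicate 2 (0.0154 and 0.0104). The others were blood endothelium without CMC replicate 2 or CMC + COL17-5 replicate 3 (0.0159 and 0.029), melanocyte without CMC + COL17-5 replicate 2 (0.0068), sebocyte without CMC replicate 3 (0.0262) and Wnt without CMC + COL17-5 replicate 3 (0.029). The mitochondrial list was also called on all 6 samples with DESeq2 (0.0203) and without the filter (0.0286). With an estimated correlation on all 6 samples its adjusted p was 0.938, and those of the 8 lists ranged from 0.938 to 0.996.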

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

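DESeq2 with a size threshold and the annotation terms of alternative calls were chosen after the data were seen. The count of called genes stayed at 0 under RLE, upper-quartile and no scaling factors, limma-voom with or without weights, robust shrinkage, a CPM filter, log2(FPKM + 1), protein-coding genes only, removal of muscle, fat and hair genes, a size threshold, an adjusted p under 0.1, and without each library in turn (0 to 0). It was 69 with DESeq2 (51 with the size threshold), 50 without the low-count filter, and 1 with log2(FPKM + 0.1) with or without the filter. DESeq2 and the unfiltered test shared 48 genes. Without the filter 36026 genes were tested and edgeR's prior degrees of freedom were 13.998 in place of 3.31, and the cause of the other differences was not tested. Annotation terms numbered 33 among DESeq2's calls and 58 among the unfiltered calls, where the main test gave none to test. Both had neutrophil chemotaxis (adjusted p = 2.86e-08 and 2.99e-08) and leukocyte chemotaxis among lower genes and the response to unfolded protein (0.00339 and 9.34e-05) among higher genes. The unfolded protein term rested on 3 of 14 annotated higher genes with DESeq2 and 3 of 6 without the filter. Without the filter the only chaperone genes among the higher calls were Hsph1, Hspa1a and Hspa1b. Hspa1a and Hspa1b are near-identical copies with levels uncertain one by one, yet Fisher's test counts them as separate genes.

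The 11 called lists became 0 with an estimated correlation and 0 with fry's directional test, which ask different questions or allow for correlated genes. The mixed test of fry called 2 lists, antimicrobial (adjusted p = 0.0378) and heat shock and immediate early (0.00763). Only the antimicrobial list was among the 11. Leaving out 1 library gave 11 to 20 lists, and the other settings 8 to 16. Inflammatory, neutrophil, erythrocyte, muscle, hair and glycolysis lists lost their call only with an estimated correlation and fry, among the settings that could test them. Calls against camera's direction on all 6 samples appeared for the elastic fibre list (adjusted p = 0.0368 without CMC + COL17-5 replicate 1, 0.0236 to 0.971 without 1 library) and the myofibroblast list (0.0249 without CMC replicate 2, 0.0184 to 0.547). They also appeared for the interferon list (0.0159 without CMC replicate 3 and 0.0195 without CMC + COL17-5 replicate 1, 0.0156 to 0.959) and the adipocyte list (0.000267 without CMC replicate 3, up to 0.581). For the elastic fibre and interferon lists camera's direction was lower, although their medians were 0.03 and 0.02. The antimicrobial list turned without its shared genes (adjusted p = 0.672). Causes were not tested. Over all lists, 824 results under an alternative were the same, 58 gained a call and 52 lost one in camera's direction on all 6 samples. Another 6, those just described, went against that direction. The tally leaves out protein-coding genes only and fry's mixed test. Over the named genes 640 were the same and 27 gained a call, 14 with DESeq2 and 13 without the filter.

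Col17a1 stayed uncalled throughout, with log2 fold changes from -0.02 to 0.34 without 1 library. The first principal component, 28.1% of variance, held 25.0% without the low-count filter, 29.7% with the CPM filter and 32.5 to 36.1% without 1 library, where fewer samples share the variance.

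With the replicate number as a block, edgeR called 0 genes and camera 10 lists. Deviations of same-numbered libraries correlated at -0.16, -0.08 and 0.13. CMC replicates 1 and 2 correlated best with another number (0.15 and 0.22), and CMC replicate 3 with its own. No pairing by number was seen across the replicates, but deviations from means of 3 samples cannot exclude one. At the depth, spread and 3 samples per group of these data, 7.46% of simulated 1.5-fold changes and 59.7% of 2-fold changes were recovered. The simulation had 200 genes changed, and which of these settings limits the recovery was not tested.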

Other observations

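The lists for the clock, glucocorticoid response and chaperones, the clock difference without Per2, the splits for lists, DESeq2, unfiltered calls and the inflammatory median, and the leukocyte and blood tests were chosen after the result was seen; the 3 predictions on heat shock genes and Per1 were prompted by that pattern in these data and written before their lists were computed, with some genes already seen left out. Genes of the endoplasmic reticulum chaperone list were above 0 in 19 of 19 in CMC + COL17-5, with a median log2 fold change of 0.26. The list holds chaperones, which fold secreted proteins, but also transcription factor genes (Xbp1 and Ddit3) and genes of protein degradation (Syvn1, Sel1l and Herpud1). Hspa5, the main chaperone of the endoplasmic reticulum, had 549.5 ± 70.4 CPM in CMC and 812 ± 171 CPM in CMC + COL17-5, a log2 fold change of 0.56, and Hyou1 one of 0.55. For both, CMC + COL17-5 replicate 1 lay below CMC replicate 3 (617 against 619 CPM for Hspa5). In that replicate Calr and Pdia3, at 651 and 618 CPM, lay below their CMC means of 688 and 666 CPM. The groups did not overlap for Herpud1, Sdf2l1, Creld2, Syvn1 and Dnajc3, and overlapped for the rest of the list. 2 of the 19 passed adjusted over the list alone and 0 over all genes with edgeR, and camera gave adjusted p = 1.45e-13, but adjusted p = 0.123 with an estimated correlation. Genes of the cytosolic heat shock list were above 0 in 17 of 18, with 4 passing adjusted over the list alone and 0 over all genes (camera adjusted p = 9.26e-17, and adjusted p = 0.0249 with an estimated correlation). The 4 include Hsph1, Hspa1b and Hspa1a, which prompted the list. It also holds the mitochondrial chaperonin genes Hspd1 and Hspe1 and the transcription factor gene Hsf1. Clock genes of the Per and Dbp phase were above 0 in 10 of 11, with 3 passing adjusted over the list alone and 0 over all genes (camera adjusted p = 1.27e-09, and adjusted p = 0.0249 with an estimated correlation). Glucocorticoid-induced genes were above 0 in 9 of 16, with Tsc22d3 at 0.50 (called by DESeq2, adjusted p = 0.0156), Fkbp5 at 0.60 and Pdk4 at -1.29. 2 passed adjusted over the list alone and 0 over all genes with edgeR (camera adjusted p = 0.0105, but adjusted p = 0.123 with an estimated correlation). The groups did not overlap for Pdk4, but CMC replicate 2 stood at 186 CPM against 54.6 and 53.1 in CMC replicates 1 and 3. Fkbp5 in CMC + COL17-5 replicate 1, at 60.9 CPM, lay within the CMC range of 57.4 to 69.5 CPM. The clock genes Per2 and Per3 had log2 fold changes of 1.25 and 0.68, while Bmal1 had -0.11, Dbp 0.09, Nr1d1 -0.04, Usp2 0.08 and Tef 0.13. Camera's p-values for these lists were adjusted over the added lists alone. They are not comparable with those adjusted over the 41 fixed lists. These added lists were chosen on these samples and are not independent evidence.

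Among single genes chosen after their values were seen, Ucp1, the uncoupling protein of brown fat, had 1306 counts in CMC replicate 2, 67 in CMC replicate 1 and 0 or 1 in the other 4 libraries. Ighg2b, an immunoglobulin constant region gene, had 6 to 9 counts in the CMC libraries and 32 to 44 in the CMC + COL17-5 libraries, with adjusted p = 0.378 with edgeR, 0.00303 with DESeq2 and 0.037 without the filter.

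With 6 samples there are 10 splits into 3 and 3, too few for a share under 0.05. For genes called by edgeR the real split and the highest other split both gave 0, and 10 of 10 splits gave as many. For lists the real split gave 11 and the highest other 25, and 9 of 10 gave as many. For DESeq2 the values were 69 and 187, with 2 of 10 as many, and for edgeR without the filter 50 and 160, with 3 of 10. The split that calls most genes sets CMC replicates 1 and 2 with CMC + COL17-5 replicate 1 against the rest with DESeq2 and without the filter, and edgeR called 0 in it.

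Inflammatory mediator and neutrophil genes were lower in CMC + COL17-5 with camera's preset correlation, but adjusted p = 0.313 with an estimated correlation for both lists, and skeletal muscle genes were lower too (30 of 30, median -1.07). A smaller share of all leukocytes would lower macrophage genes alike. The macrophage median lay 0.90 above the neutrophil median (bootstrap interval 0.52 to 1.58 over genes), so the 2 lists did not fall alike here. The libraries' differences did not overlap between groups, which chance gives in 10% of cases. This test was chosen after both medians were seen, and its interval treats correlated genes as independent. It is therefore not independent evidence against a smaller share of leukocytes. More blood in the CMC tissue may contribute and cannot be told apart. With haemoglobin share as a covariate the inflammatory median was -1.49, but its bootstrap interval over genes, -2.79 to -0.53, is wide around the original -1.14. The erythrocyte median went from -0.99 to -0.16. That fall follows from the covariate, since haemoglobin genes belong to the erythrocyte list, so it does not show that the covariate captures blood. The inflammatory median was larger than in every other split (1.14 against 0.93 at most, 1 of 10 splits), the neutrophil median was not (0.98 against 1.20), and the splits are too few for a share under 0.05. An effect of the treatment stays open, as do fewer neutrophils or a lower activity of the cells present, none of which was tested.

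Heat shock genes and Per1 had higher values in CMC + COL17-5, with 0 passing over all genes with edgeR. A different hour of collection for the groups is a candidate explanation, but the labels give no hour. Genes of the Per and Dbp phase other than Per1 stood 0.48 above those of the Bmal1 phase on the log2 scale, as it predicts. The interval of 0.22 to 0.77 was a bootstrap over genes and treats correlated genes as independent. The other 9 splits gave 0.37 at most, but chance makes the real split the largest in 10% of cases, so the splits cannot decide. Per2 and Per3 carry much of the difference, and Dbp and Nr1d1 stayed near 0. Without Per2, which DESeq2 called, the difference was 0.38 against 0.33 at most. Glucocorticoid exposure cannot be told apart, since the median of 14 induced genes was 0.0264 with an interval of -0.12 to 0.28 and its members went both ways. A general protein-folding response cannot be told apart either. The median was 0.23 over 17 genes of the endoplasmic reticulum chaperone list (interval 0.16 to 0.49), between the bounds set for and against it. The treatment itself stays open, since it divides the samples the same way.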
